A study of Mus musculus with 6 samples.

How the data were processed

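The series holds 6 samples from mouse cells of the C57BL/6 strain. Neural stem cells (NSCs) had been derived from embryonic stem cells and were kept at passages 25 to 30. Neurons were made from them over 11 days, 4 in a first medium and 7 in a second, and were sorted by flow cytometry for RedStar, a red fluorescent reporter under the Tau (Mapt) promoter. Per the labels' protocols, chromatin was fixed in 1% formaldehyde, sheared to about 300 bp and immunoprecipitated with antibodies against H3K4me3, a mark of active or poised promoters, and H3K27me3, the mark laid down by Polycomb repressive complex 2. Each antibody was sequenced in 1 library per cell type, and each cell type had 1 input library. Total H3 and IgG precipitations were made but, per the labels, not sequenced.

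The submitters' processing notes name FastQC, Bowtie, SAMtools and SICER, without versions, and the mouse build mm9. Aligner settings, duplicate handling and the SICER window and gap settings are not given in the sources used here. For each immunoprecipitated library the authors deposited a peak list, called on that library alone against its input, and a table that pairs each Ensembl gene with a peak. The peak bounds move in steps of 200 bp and all listed peaks have a false discovery rate (FDR) under 0.001, which was checked on the files.

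Per peak, the authors deposited the count of immunoprecipitated reads, the count of control (input) reads, a p-value, an FDR and a fold over input. The deposited fold is the ratio of the read counts times a constant per library, and this constant was read as control total over immunoprecipitated total. The constants were 1.024 for NSC H3K4me3, 0.993 for neuron H3K4me3, 1.398 for NSC H3K27me3 and 1.05 for neuron H3K27me3. The peak's fold and p-value are the authors' own and were used only to rank, filter or describe peaks within a list. A score column (minus 10 times the log10 of the p-value) in the deposited gene tables was not used. Positions of genes and peaks are other deposited columns and are printed as the authors' files give them, on mm9. The inputs had no processed file used here, so input reads are known only inside peaks, and absolute library totals are unknown.

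A start site was taken as the start of a plus-strand gene or the end of a minus-strand gene in the deposited tables. The universe was the 18778 genes named in any of the 4 tables, 4178 of them without a symbol, so it leans towards genes near peaks. Under the rule fixed before the data were examined, a gene counted as marked when its gene table gave it a peak within 1000 bp of the start site. This is called the table rule. Once the data were examined, 2 properties of the tables came to light. The neuron H3K4me3 table holds peaks at FDR under 0.001, whereas the other 3 hold only peaks at FDR under 1e-20. The tables also often name a farther peak although a listed peak lies at the start site. That held for 1471 genes in NSC H3K4me3, 1732 in neuron H3K4me3, 975 in NSC H3K27me3 and 840 in neuron H3K27me3. A peak-list rule was therefore added after seeing the data, in which any peak of the full list within 1000 bp of the start site marks the gene. Both are printed, and a gene is described as having gained or lost a mark by both rules unless the text says by which rule.

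Lost means marked in NSCs and not in neurons, and gained the reverse. These are presence or absence of calls, not tests, since there was 1 library per cell type and antibody. Overlap of peaks was found with bedtools 2.31.1 at a minimum of 1 bp, beside 20 random placements of the peaks on the same chromosomes. Exact (Clopper-Pearson) 95% binomial intervals cover counting error only. For the 22 gene lists fixed beforehand, counts were set beside 10000 random lists of the same size. For gains and losses the random genes had the same NSC state and the same class of NSC peak width, from 5 classes by rank that differ in size where widths tie. A match on such a class of NSC peak fold was added after the data were seen. The number of genes with both marks expected of independent marks is not used here, since genes without a nearby peak are left out of the universe, which raises that number. Percentages of random lists describe these libraries and are not p-values. Random genes were drawn singly, so neighbouring genes that share a peak, as in the Hox clusters, counted as separate draws. Percentages for such genes can be too extreme. The lists hold 636 symbols besides the olfactory receptors, 113 of which were in none of the tables and were not scored, and 10 were matched through an older symbol in a RefSeq table of the GRCm38.p6 assembly that was used for names alone. Calculations used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9.

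The distance and list-drawing steps were tested on simulated data. For NSC H3K27me3 over 18778 genes, 0 of 1000 start-site distances differed from a brute-force search. Of 100 simulated lists of 40 genes in which marked genes were drawn 3 times as often, 93 had as many marked genes in under 5% of random lists, as did 4 of 100 lists without such enrichment.

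Genes are named by a rule fixed before the data were examined. It holds 21 genes that are always named where scored, up to 3 members of each list per change or fate, by widest peak, and up to 8 genes per antibody and direction from all genes, by widest peak, with no peak of that mark within 10 kb in the other cell type. Genes named outside the rule are said to be so. Of the 21, Aqp4, Sox10, Pou5f1 and Nanog were in none of the tables and were not scored. Some genes that meet the rule are not reported here. Settings varied were the strongest 50% of each list, equal numbers of peaks, a minimum width, merged peaks, autosomes, other overlaps, other windows, stricter absence and random lists without the width match.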

Results

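Neural stem cells (NSCs) and the neurons made from them, both of mouse origin, were compared for a mark of active or poised promoters (H3K4me3) and a Polycomb mark (H3K27me3). The neurons were at day 11 of differentiation and had been sorted for a reporter under the promoter of Mapt, the gene of the axonal microtubule protein tau. There were 4 immunoprecipitated libraries, 1 per cell type and antibody, and 2 inputs, so there were no replicates and no difference below has a replicate check. Reads inside called peaks numbered 3623654 in NSC H3K4me3, 983266 in neuron H3K4me3, 3272324 in NSC H3K27me3 and 3161819 in neuron H3K27me3. These sums cover 57.35, 24.67, 173.17 and 146.44 Mb of called peaks, at 63.2, 39.9, 18.9 and 21.6 reads per kb.

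The neuron H3K4me3 library was less enriched than the NSC library. In 397 H3K4me3 peaks with the same bounds in both cell types, neurons had 0.399 times the immunoprecipitated reads of NSCs and 0.775 times the input reads. If the input totals differed as the input reads in these peaks did, the fold constants put the neuron H3K4me3 library total at about 0.80 times that of NSCs, and its reads in these shared peaks stood at 0.50 of what the totals alone would give. For H3K27me3, in 113 such peaks, neurons had 0.98 times the immunoprecipitated reads and 0.783 times the input reads, and the same estimate for the totals was 1.04. These 113 are few beside the 17607 NSC H3K27me3 peaks that overlapped a neuronal one. Equal enrichment of the H3K27me3 libraries was therefore not shown. Input reads were not even along the genome in either cell type. In H3K27me3 peaks on chromosome 1 they stood at 1.46 times the median autosome in NSCs and 1.48 times in neurons.

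**Figure D1:**
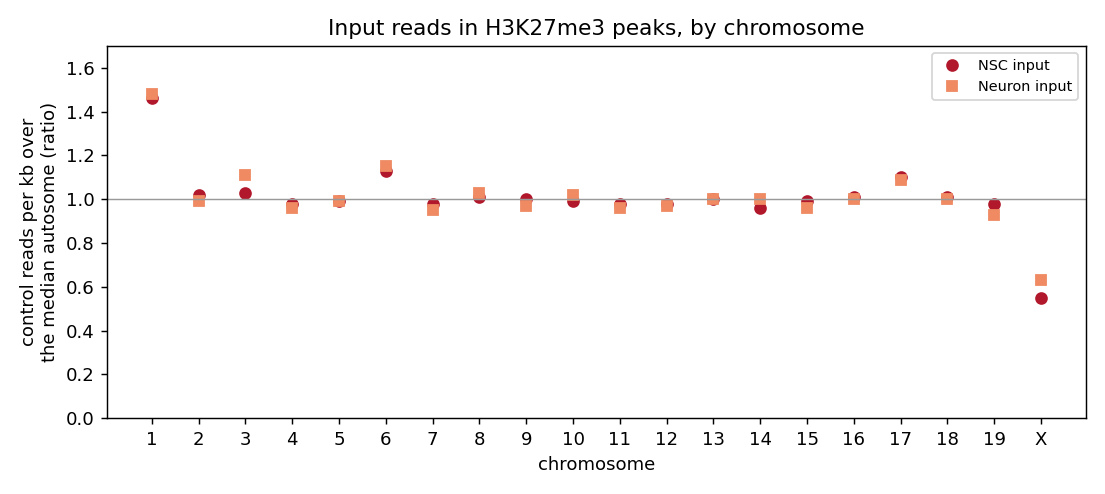
Input reads per kb in H3K27me3 peaks of each chromosome as a ratio to the median autosome; circles are the NSC input and squares the neuron input. Chromosome 1 stands at 1.46 and 1.48, and chromosome X at 0.55 and 0.63.

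The first question was how much of each mark's landscape the stem cells and neurons shared. H3K4me3 was called in narrow peaks, 30416 in NSCs with a median width of 1600 bp and 14846 in neurons with 1400 bp. Most neuronal H3K4me3 peaks lay where NSCs had one: 78.8% of them overlapped an NSC peak (95% interval 78.1 to 79.5), against 4.4% for random placement. Of the NSC peaks, 37.0% overlapped a neuronal peak (36.5 to 37.6), against 2.2%. With the strongest 50% of each list, 99.2% of neuronal H3K4me3 peaks overlapped an NSC peak. With equal numbers of peaks, 71.1% of NSC peaks overlapped a neuronal peak.

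H3K27me3 lay in broader domains, 26539 in NSCs with a median of 4800 bp and 36053 in neurons with 3000 bp. The neuronal domains were more numerous and shorter, although at FDR under 1e-20 there were 6981 in NSCs and 6788 in neurons. Of the NSC domains, 4748 overlapped more than 1 neuronal peak. Of the NSC domains 66.3% (65.8 to 66.9) overlapped a neuronal one, against 12.8% by random placement, and of the neuronal domains 61.2% (60.7 to 61.7) overlapped an NSC one, against 11.1%. The widest domain in NSCs covered the Hoxc cluster, on chromosome 15 from 102718400 to 102957599, and was 239.2 kb long. The widest in neurons covered the Hoxb cluster, on chromosome 11 from 96110800 to 96239199, and was 128.4 kb long, and NSCs had a domain of 127.8 kb at the same place. There NSCs had 5962 reads over 903 input reads, a fold of 9.23, and neurons 3822 over 721, a fold of 5.57. Under a reciprocal overlap of 50%, the shared shares of H3K27me3 peaks dropped to 33.1% and 24.3%.

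H3K4me3 stood at the start sites of most genes and H3K27me3 at a minority. The table rule gave H3K4me3 at 10980 of 18778 genes in NSCs and 9690 in neurons, and H3K27me3 at 1453 and 955. By the peak-list rule the numbers were 13218 and 11580 for H3K4me3 and 3598 and 3355 for H3K27me3. The housekeeping genes were marked with H3K4me3 in NSCs at all 21 scored members and in neurons at 19, and with H3K27me3 at none (peak lists). Gapdh and Actb, of glycolysis and the cytoskeleton, carried H3K4me3 in both cell types. Neural stem cell genes were likewise marked, 27 of 32 with H3K4me3 in each cell type by the peak lists, and 20 and 18 by the table rule. Nes, Sox2, Olig2 and Hes5, which encode an intermediate filament and transcription factors of neural progenitors, had H3K4me3 in NSCs and in sorted neurons and no H3K27me3 in either by the peak lists. The Olig2 peak spanned 13400 bp in NSCs and 10000 bp in neurons. The gene table had named a farther peak for Sox2 in both cell types.

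**Figure D2:**
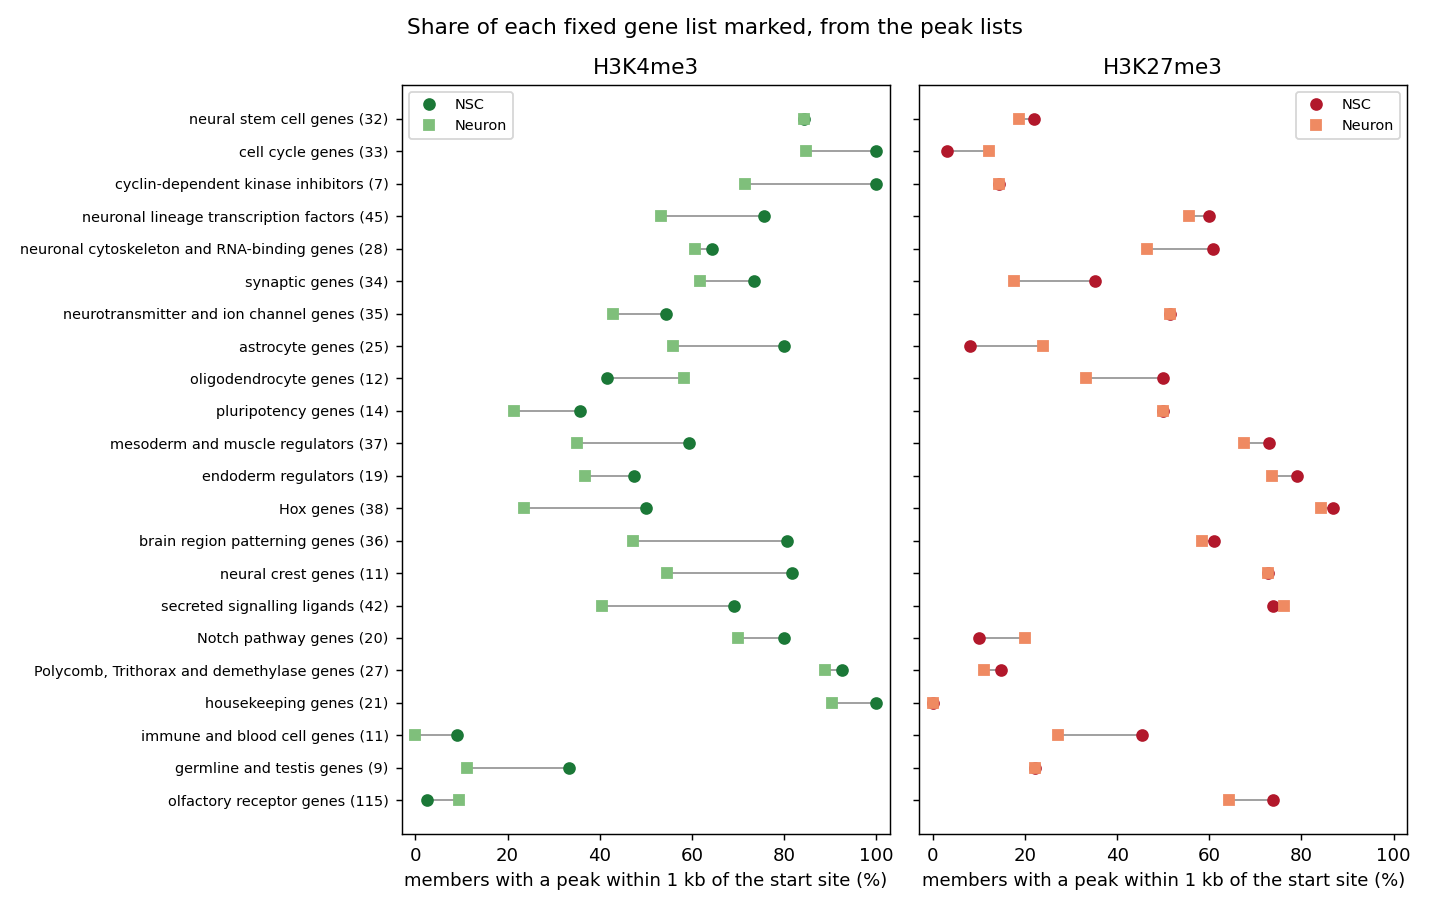
Share of the scored members of each fixed gene list (number in brackets) with a peak within 1 kb of the start site, from the peak lists; circles are NSCs and squares neurons, H3K4me3 on the left and H3K27me3 on the right. All 33 cell cycle genes had H3K4me3 in NSCs and 28 had it in neurons, and 33 of 38 Hox genes had H3K27me3 in NSCs against 32 in neurons.

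The next comparison asked which start sites differed in H3K4me3 between the stem cells and the neurons. Losses outnumbered gains. By the table rule 1998 genes had lost H3K4me3 in neurons and 708 had gained it. By the peak lists 1794 had lost it and 156 had gained it, and 1068 losses and 85 gains were shared by both rules. The peak lists thus held 53.5% of the table-rule losses and 12.0% of its gains. At the rest, the other cell type had a listed peak within 1000 bp that its gene table did not name for that gene. Genes that lost the mark included S100b, Ccna2, Eomes and Hoxd1, and the few gains included the neuronal genes Dcx, Stmn3 and Camk2a.

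Of 20 astrocyte genes with H3K4me3 in NSCs, 6 had lost it in neurons by the peak lists, against 1.48 expected from width-matched random lists, and 0.19% of random lists lost as many. By the table rule it was 6 of 17, and 2.72% of random lists lost as many. S100b, which encodes a calcium-binding protein of astrocytes, the acyl-CoA synthetase gene Acsbg1, the adhesion receptor gene Cd44 and the matrix protein genes Sparcl1 and Sparc had lost it by both rules. Nfib had lost it by the peak lists alone, and Sparc and Nfib are named after their values were seen. In NSCs, the Acsbg1 peak held 338 immunoprecipitated and 54 input reads over 5200 bp, and the nearest neuronal H3K4me3 peak was 71323 bp away. The S100b peak was 2600 bp wide with 107 and 31 reads, and the nearest neuronal peak was 15399 bp away. Gfap, of the astrocyte intermediate filament, had neither mark at its start site in either cell type. When random lists were matched on the NSC peak's fold in place of its width, 16.0% lost as many as the astrocyte list.

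All 33 cell cycle genes carried H3K4me3 in NSCs by the peak lists, and 5 had lost it in neurons, against 1.7 for random lists, of which 2.38% lost as many. All 5 held under both rules. Ccna2, of cyclin A2, was among them, with 323 reads over 43 input reads in NSCs and no neuronal peak within 18673 bp. The other 4, Cdk1, Ccnb2, Bub1b and Cdc6, act in mitosis and DNA replication and are named after their values were seen. By the table rule 8 of 31 had lost the mark, and 9.78% of random lists lost as many. With the match on fold, 22.3% of random lists lost as many as the 5 of the peak lists.

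Some regulators of development lost H3K4me3 as well, often where H3K27me3 was present in both cell types. Of 19 Hox genes with H3K4me3 in NSCs, 11 had lost it in neurons by the peak lists, against 5.44 in width-matched random lists, of which 0.3% lost as many. The table rule gave 5 of 9 (7.38%), and Hoxd1, Hoxd8, Hoxa2 and Hoxa4 held under both rules. With the match on fold, 10.4% of random lists lost as many as the 11, and where absence required no peak within 10 kb, 4 of 19 counted as lost. Among brain patterning genes 12 of 29 had lost H3K4me3 (3.93% of random lists as many), and among neuronal lineage transcription factors 12 of 34 (12.5%). The table rule gave 6 of 19 (25.0%) and 16 of 23, a loss that none of 10000 random lists reached. Eomes, the T-box factor of cortical intermediate progenitors, had a 3400 bp H3K4me3 peak in NSCs, and the nearest neuronal one was 27870 bp away. Its H3K27me3 domain was 8600 bp wide in NSCs and 9400 bp in neurons. Emx1, Gbx1, Isl1, Lhx8, Neurod2 and Neurog1 also lost H3K4me3 and kept H3K27me3 by the peak lists, as did the ligand genes Fgf8, Wnt4 and Wnt9a. Of 29 secreted ligand genes 14 had lost H3K4me3, and 15.6% of random lists lost as many, against 10 of 14 and 0.2% by the table rule. Losses were 9 of 22 for mesoderm, 2 of 9 for endoderm and 3 of 9 for neural crest genes by the peak lists. With the match on fold, 42.8%, 90.0% and 78.0% of random lists lost as many as these, respectively. With that match, none of the 22 lists had a loss of H3K4me3 that under 5% of random lists reached.

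Few genes had gained H3K4me3. Dcx, of the microtubule protein doublecortin in migrating neurons, had a neuronal H3K4me3 peak of 1000 bp with 33 reads over 5 input reads, and the nearest NSC peak was 384146 bp away. Stmn3, a neuronal stathmin gene, had 37 reads over 9 in neurons, and Camk2a, a synaptic kinase gene, had 90 over 17, with the nearest NSC peaks 4595 and 2873 bp away. Kcna2, Cdh8 and Csmd1 had neuronal peaks of 2000, 2600 and 2600 bp and no NSC peak within 10 kb. The potassium channel gene Kcna2, the cadherin gene Cdh8 and Csmd1, of a complement regulator, also carried H3K27me3 in both cell types by the peak lists. Pax6, of the radial glial transcription factor, had an H3K4me3 peak near its start site in neurons by the peak lists, with 28 reads over 6, and its nearest NSC peak was 5947 bp away. Oligodendrocyte genes were marked with H3K4me3 at 5 of 12 members in NSCs and 7 in neurons, and Ugt8a was among the gains by both rules. Mbp, of myelin, had no H3K4me3 in either cell type.

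The loss of H3K4me3 went with the size of the NSC peak. By the peak lists 46.0% of the 2137 genes with the narrowest NSC peaks lost the mark and 4.8% of the 2578 with the widest, the outer groups of 5 by width. At an FDR under 1e-20 in both lists, 5004 genes had lost H3K4me3 and 35 had gained it. That limit cut the less enriched neuron list more. Marked genes went from 13218 to 12479 in NSCs and from 11580 to 7510 in neurons. Of the 156 gains of the peak lists, 43 lay on chromosome 1, where input reads were raised.

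**Figure D3:**
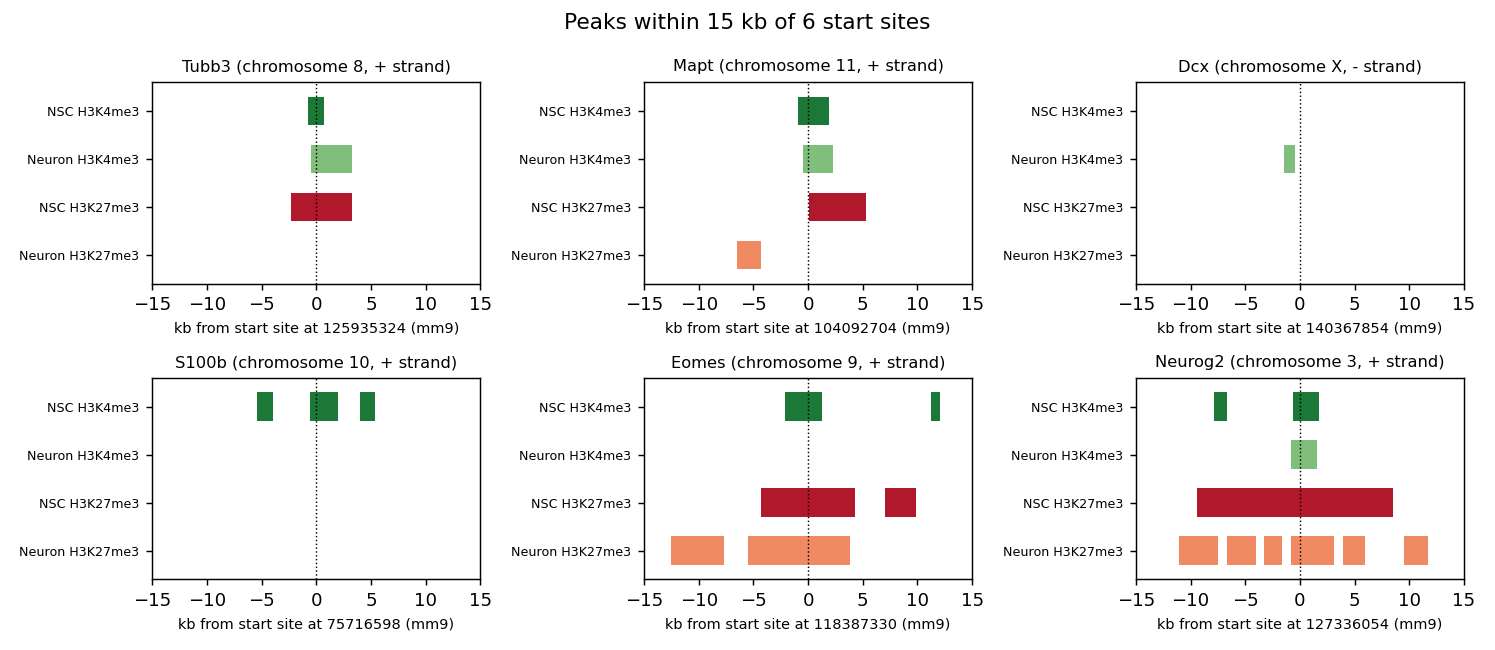
Called peaks within 15 kb of the start sites (dotted line, position 0) of Tubb3, Mapt, Dcx, S100b, Eomes and Neurog2, in kb on mm9, with a line per library. Tubb3 has an H3K27me3 peak in NSCs and none in neurons, Dcx has H3K4me3 in neurons, and S100b and Eomes have H3K4me3 at the start site in NSCs.

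The same comparison was made for H3K27me3. With the table rule 831 genes had lost it in neurons and 333 had gained it. By the peak lists 911 had lost it and 668 had gained it, with 247 losses and 86 gains shared by both rules. The peak lists held 29.7% of the table-rule losses and 25.8% of its gains, and at the rest the other cell type had a listed peak within 1000 bp. As for H3K4me3, loss went with the size of the NSC peak. By the peak lists 42.8% of the 710 genes with the narrowest NSC H3K27me3 peaks lost the mark, and 6.8% of the 725 with the widest. Tubb3, Stmn3 and Pclo were among the losses, although in the full peak lists their gene lists lost no more than many random lists did. Most marked Hox genes kept the mark by either rule, whereas patterning and ligand genes mostly kept it by the peak lists alone. Gja1 and Ccnd2 were among the gains.

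Tubb3, of the neuronal beta-tubulin, had a 5600 bp H3K27me3 peak in NSCs with 107 reads over 51 input reads, and the nearest neuronal peak was 83525 bp away. Its H3K4me3 was present in both cell types, in a peak of 1400 bp in NSCs and 3800 bp in neurons. Mapt, whose promoter drove the reporter, had H3K4me3 in both cell types, 2800 bp wide in each. It had a 5200 bp H3K27me3 peak in NSCs by the peak lists, and the nearest neuronal one was 4305 bp from its start site. Uchl1, of a neuronal ubiquitin hydrolase, and Stmn3 also lost H3K27me3 by both rules, with 137 and 140 NSC reads over 56 and 68 input reads. Of 17 neuronal cytoskeleton and RNA-binding genes with H3K27me3 in NSCs 5 had lost it, the last being Ina, named after its values were seen, and 56.7% of random lists lost as many (5 of 7 and 41.0% by the table rule). Of 12 synaptic genes with the mark 6 had lost it, against 3.49 in random lists, of which 9.68% lost as many, and the table rule gave 2 of 3. By the peak lists, 8 had lost it with equal numbers of peaks and 2 with absence within 10 kb. Among the 6 was Pclo, of a presynaptic scaffold, with 184 reads over 97 in NSCs and the nearest neuronal peak 1022 bp away. Camk2a and Shank1 were among them by the peak lists.

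Transcription factor genes that lost H3K27me3 and kept H3K4me3 by the peak lists included Bcl11b, Pou4f1, Onecut1 and Lhx2, of neuronal and forebrain identity. The Pou4f1 domain was 18400 bp wide in NSCs, and the nearest neuronal peak was 6217 bp away. Erbb4 and Nrp2, of a neuregulin receptor and a semaphorin receptor, lost NSC domains of 18200 and 9400 bp on chromosome 1. Of the 33 Hox genes with H3K27me3 in NSCs 1 had lost it by the peak lists, against 2.22 in random lists, of which 33.9% lost as few. Of 31 marked ligand genes 1, Wnt7a, had lost it, against 6.73, and 0.45% of random lists lost as few. The table rule gave Hox losses of 5 of 32, where 0.04% of random lists lost as few, and ligand losses of 8 of 16, where 34.8% did. Hox genes are not separate draws, since 1 NSC domain marked all 9 scored Hoxc genes and 1 all 9 scored Hoxd genes. The Hox percentages are therefore likely too extreme.

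Gains of H3K27me3 were seen at 4 of 23 astrocyte genes that lacked it in NSCs, against 0.93 in random lists, of which 1.17% gained as many. These were Gja1, of the gap junction protein connexin 43, which held under both rules, and Aldh1l1, Slc4a4 and Chi3l1, named after their values were seen. The table rule gave 1 of 25. Gja1 had a neuronal domain of 10600 bp with 184 reads over 76, and the nearest NSC peak was 4737 bp away. Of 32 cell cycle genes 3 had gained the mark (5.82% of random lists as many), and 1 of 33 by the table rule, among them Ccnd2, of cyclin D2, with a neuronal domain of 8600 bp and no NSC peak within 70647 bp. Slc17a6, of the vesicular glutamate transporter VGLUT2, gained a 14000 bp domain, with the nearest NSC peak 2763 bp away. Kank2 both lost H3K4me3 and gained an 18200 bp H3K27me3 domain. Where absence required no peak within 10 kb, the table rule left 65 losses and 53 gains and the peak lists 322 and 423. Of the 668 gains of the peak lists 12.9% lay on chromosome 1, which holds 7.9% of the genes.

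**Figure D4:**
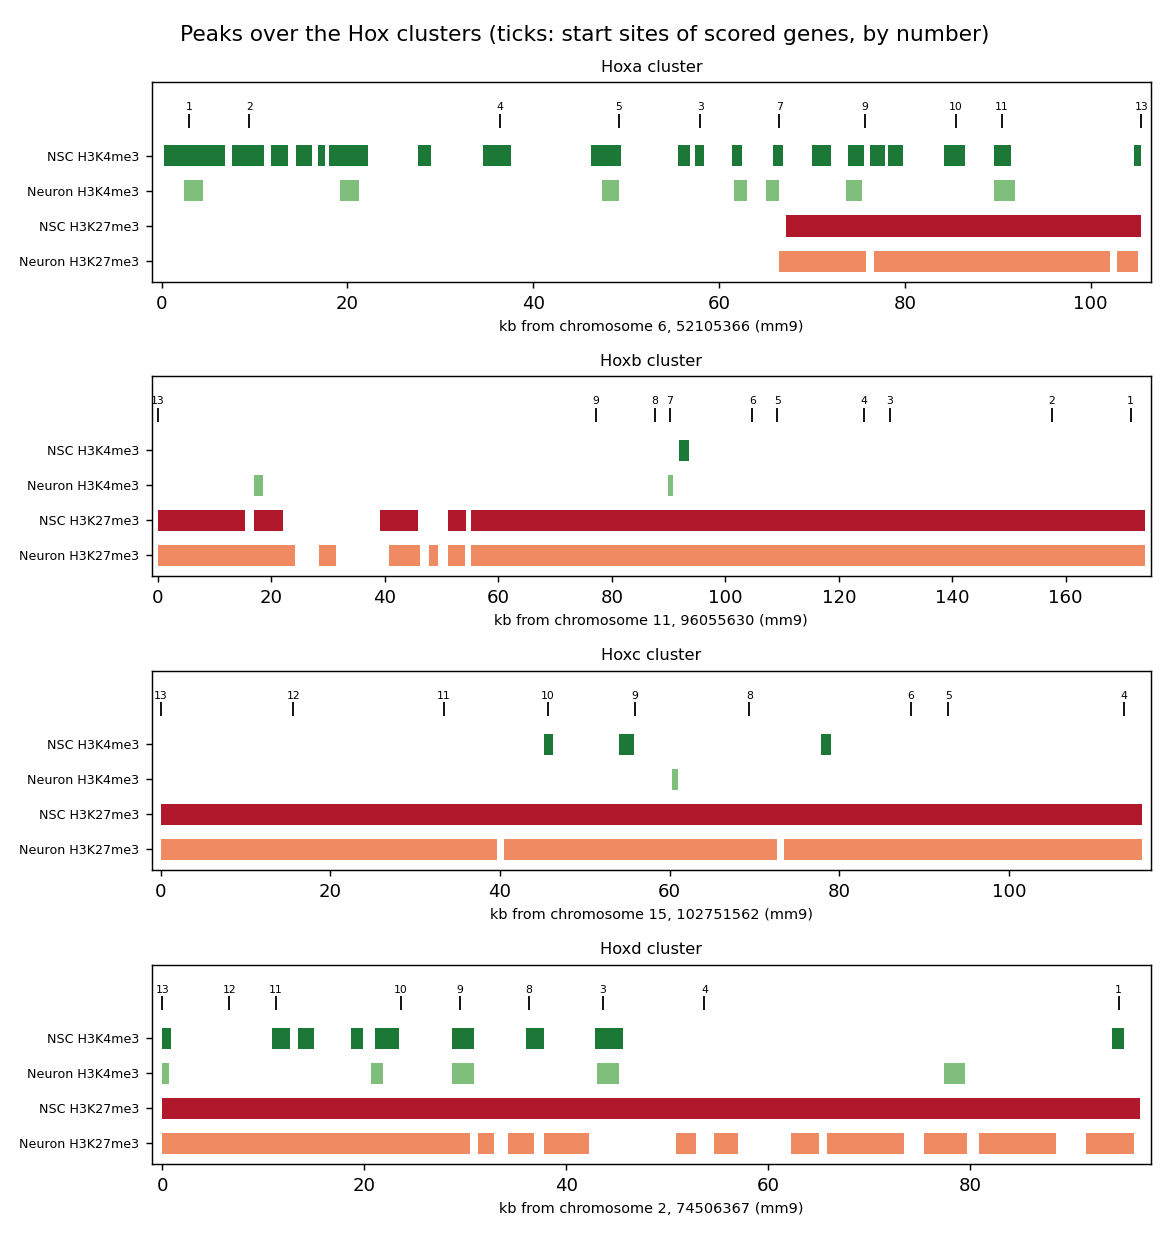
Called peaks over the 4 Hox clusters in kb on mm9, with a line per library and ticks at the start sites of scored genes. H3K27me3 covers 36.2% of the Hoxa cluster in NSCs and 35.1% in neurons, at the end away from Hoxa2 and Hoxa4, and H3K4me3 covers 40% and 12.0%.

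The Hox clusters differed from one another. H3K27me3 covered 85.6% of the Hoxb cluster in NSCs and 89.7% in neurons, and 100% and 98.6% of Hoxc. Over Hoxd, on chromosome 2 from 74506367 to 74603200, NSCs had 1 domain across the whole cluster and neurons had 11 peaks that covered 72.7%. Over Hoxa, on chromosome 6 from 52105366 to 52210797, the end with Hoxa2 and Hoxa4 had no H3K27me3 peak in either cell type. All 10 scored Hoxa genes had H3K4me3 in NSCs and 5 had it in neurons. Covered length of H3K4me3 over Hoxa dropped from 42.2 kb to 12.6 kb, and over Hoxd from 15.8 kb to 8.2 kb. Over the whole genome it dropped from 57.35 to 24.67 Mb in the less enriched neuron library, so a drop was not particular to these clusters.

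The last comparison followed genes that carried both marks in the stem cells, a state often called bivalent, although a population of cells cannot show both marks on the same nucleosome. The table rule gave 436 genes with both in NSCs and 156 in neurons. By the peak lists 1601 genes carried both in NSCs and 861 in neurons. Among all peaks, 10.9% of NSC H3K4me3 peaks overlapped an NSC H3K27me3 peak, against 9.0% by random placement, and 12.1% of neuronal H3K4me3 peaks overlapped a neuronal H3K27me3 peak, against 8.7%. Of the genes with H3K27me3, 44.5% had H3K4me3 in NSCs and 25.7% in neurons (peak lists), and 30.0% and 16.3% by the table rule.

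Genes with both marks in NSCs went separate ways. Of the 436 of the table rule, 81 kept both marks, 148 had H3K4me3 only, 107 had H3K27me3 only and 100 had neither. Of the 1601 of the peak lists, 591 kept both, 334 had H3K4me3 only, 597 had H3K27me3 only and 79 had neither. With equal numbers of peaks from the peak lists, 405 had H3K27me3 only and 361 had H3K4me3 only. The lower enrichment of the neuron H3K4me3 library could have added to the H3K27me3-only group. It could also have added to the fall in genes with both marks, and neither was tested apart from it. The H3K4me3-only group of the peak lists included Tubb3, Uchl1, Pclo, Bcl11b, Pou4f1, Onecut1 and Wnt7a. The H3K27me3-only group included Gbx1, Eomes, Isl1, Neurog1, Mesp1, Alx4, Wnt9a, Slc6a4 and Hoxd1. Genes that kept both by both rules included Foxc2, Foxd3, Foxf1a, Wt1 and Snai2, which act in mesoderm and neural crest, the Notch ligand genes Dll4 and Jag2, and Nefh, Hoxa9, Hoxd9, Gdf6 and Pou4f2. Neurog2, the proneural factor, kept both by the peak lists, and its H3K27me3 domain was 18000 bp wide in NSCs. Neurons had separate H3K27me3 peaks along the same place, of 3600, 2600, 1600, 4000 and 2000 bp, with the 4000 bp peak at the start site.

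**Figure D5:**
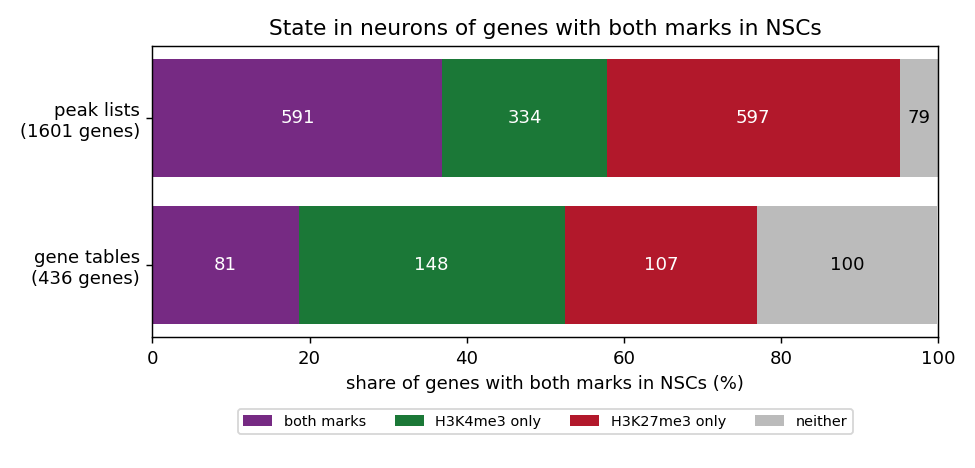
State in neurons of genes with both marks in NSCs, as a share (%) of those genes, by the table rule (436 genes) and by the peak lists (1601 genes); numbers in the bars are genes. The share with H3K27me3 only is 24.5% by the table rule and 37.3% by the peak lists.

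Many members of the developmental gene lists carried both marks. By the peak lists both marks were present in NSCs and in neurons, respectively, at 14 and 6 of 38 Hox genes, 18 and 5 of 36 brain patterning genes, 21 and 8 of 45 neuronal lineage transcription factors and 20 and 11 of 42 ligand genes. They were present at 18 and 9 of 37 mesoderm regulators, 8 and 6 of 19 endoderm regulators and 6 and 4 of 11 neural crest genes. None of 10000 random lists held as many with both marks in NSCs for these lists, except the endoderm list, for which 0.03% did. The random lists do not allow for Hox genes that share a domain. Neuronal cytoskeleton genes had both marks at 12 and 7 of 28, synaptic genes at 7 and 2 of 34, and transmitter and channel genes at 10 and 6 of 35. Of the genes with both marks in neurons by the peak lists, 68.6% had both in NSCs and 23.0% had H3K4me3 only. The order of the H3K4me3-only and H3K27me3-only fates changed with the rule and, within the table rule, with the setting.

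Apart from the olfactory receptor genes, the remaining lists moved less or held few scored genes. The counts of all of them are from the peak lists. Polycomb, Trithorax and demethylase genes had H3K4me3 at 25 of 27 members in NSCs and 24 in neurons. Notch pathway genes had it at 16 and 14 of 20, with Notch3 among the losses by both rules, and cyclin-dependent kinase inhibitor genes at 7 and 5 of 7. Pluripotency genes had H3K4me3 at 5 and 3 of 14 and H3K27me3 at 7 of 14 in each cell type. Immune and blood cell genes, markers of cells foreign to these cultures, had H3K4me3 at 1 and 0 of 11, the 1 being Kdr. Germline genes had it at 3 and 1 of 9. Olfactory receptor genes had H3K27me3 at 85 and 74 of 115 and H3K4me3 at 3 and 11. Those 115 are the receptors that lie near enough to a peak to be listed, out of 1428 such symbols in the reference table, and paralogs of this family can share reads.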

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

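The input reads, which the comparisons of the report use only through the authors' peak calls, were raised on chromosome 1 in the peaks of both antibodies. The test on strong peaks and the tests on 10 Mb bins were set out before their results were seen, and the chromosome averages were seen first. In H3K27me3 peaks, input reads per kb on chromosome 1 stood at 1.46 times the median autosome in NSCs and 1.48 times in neurons, and chromosome 6 stood at 1.13 and 1.15. In H3K4me3 peaks chromosome 1 stood at 1.39 and 1.40, and chromosome 11, at 0.98 and 0.96 in H3K27me3 peaks, stood at 1.39 and 1.45, and at 1.05 and 1.49 in H3K4me3 peaks at FDR under 1e-20. Input reads were piled up in the widest NSC H3K4me3 peak, on chromosome 11 from 3023200 to 3100199, with 15201 at a fold of 1.05. Neuronal H3K4me3 peaks within it held 5102 and 2502 input reads, at folds of 1.44 and 1.16. The chromosome 11 ratio without this place was not computed. Chromosome 17 stood at 1.27 to 1.40 in peaks of either antibody at FDR under 1e-20. Chromosome 1 also held 17.7% of the neuronal H3K4me3 peaks and 11.7% of the NSC ones, with 7.9% of the scored genes, but 6.9% and 5.9% of those at FDR under 1e-20, so the excess of peaks lay among the weaker ones.

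Reads piled up in a few places do not account for the raised input reads in H3K27me3 peaks of chromosome 1, since the median 10 Mb bin of chromosome 1 lay at 1.42 times the autosomal median in the input where it was lower. Counting them in weak peaks does not account for the ratio either, since it was at least 1.5 in both inputs when only peaks at FDR under 1e-20 were used. All of the 20 bins of chromosome 1 were over 1.2 times the autosomal median in both inputs, that is 100%, which is what a gain of the whole chromosome in the cultured cells would give, and such a gain may be the source. On chromosome 6, 3 of 15 bins passed that limit in each input, the 3 next to each other from 110000001 to 140000000. The ratio was present in both cell types, so no difference between the cell types was tested, and no karyotype was used here.

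The losses of H3K4me3 at astrocyte genes and at Hox genes were weighed against the lower enrichment of the neuronal H3K4me3 library. The match on fold was set out before its result was seen, after the width-matched values were known, and its repeats with equal numbers of peaks and with absence within 10 kb were chosen after the other values were seen. With random lists matched on NSC state and on the class of NSC peak fold, 16.0% lost as many genes as the astrocyte list and 10.4% as many as the Hox list, so lower enrichment could have contributed to both counts, and it was not excluded. Matched on width, the losses stood out with equal numbers of peaks as well, at 5 of 19 astrocyte genes (0.19% of random lists as many) and 7 of 14 Hox genes (0.66%), and with absence within 10 kb at 6 of 20 astrocyte genes (0.01%) but not at Hox genes, with 4 of 19 (71.8%). Matched on fold, the shares were 11.0% for astrocyte and 10.9% for Hox genes with equal numbers, and 5.02% and 95.4% with absence within 10 kb. The explanation stays open, since the result turned on the match, and a difference between the cell types could not be tested apart from enrichment with 1 library per group.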

How the results depend on the processing

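The peak-list settings and those without chromosome 1 were chosen after seeing the data, and the others before. A count is called moved when it changed by over 1.5 times and a share when it left its 95% binomial interval. Gene counts in every setting, peak-list settings included, were compared with the main table rule. Losses of H3K4me3 outnumbered gains in every setting, least with table peaks within 5 kb, 1943 against 824, and most in the peak lists at FDR under 1e-20, 5004 against 35. Every setting used the same less enriched neuron H3K4me3 library, so this agreement does not separate the excess of losses from lower enrichment. Losses of H3K27me3 outnumbered gains in each setting but the peak lists with absence within 10 kb, with 322 against 423. The numbers of genes marked with H3K4me3 kept within 1.5 times in every setting. Equal numbers of peaks left every table-rule count as it was, since the tables name no peak outside the lists so limited, and that setting tests nothing there. Of genes with both marks in NSCs, more had H3K4me3 only than H3K27me3 only by the table rule, 148 against 107, and within 5 kb, 188 against 136, and about as many with overlap of the start site, 99 against 98. The order was reversed with the strongest 50%, 82 against 153, with the table rule and absence within 10 kb, 21 against 79, and in every peak-list setting. A list of the strongest 50% holds 50% of the peaks by construction. For gene counts that setting cut neuron H3K4me3 alone, from 9690 to 7058 genes. It left NSC H3K4me3 at 10980, NSC H3K27me3 at 1453 and neuron H3K27me3 at 955, since those gene tables hold only peaks at FDR under 1e-20. Its moves in gene, fate and list counts follow from that uneven cut. The cause of the other moves was not tested. Of the results not listed below, 132 of 214 list counts moved with the peak lists, 44 with the strongest 50%, 33 with overlap of the start site, 45 within 5 kb and 0 with equal numbers. With peak-list settings 102 (FDR under 1e-20), 120 (equal numbers) and 123 (without chromosome 1) of 214 moved. With absence within 10 kb 44 of 82 moved by the table rule and 46 of 82 by the peak lists. Moves in the peak-list settings include the change of rule itself, which alone moved 132 of 214. Random lists without the width match moved 33 shares and kept 50. Covered length moved for 2 of 4 libraries with the strongest 50% and for none in the other settings. No paired analysis was possible because each group holds 1 library.

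With the strongest 50% of each list, peaks numbered 15208 (NSC H3K4me3), 7423 (Neuron H3K4me3), 13269 (NSC H3K27me3) and 18026 (Neuron H3K27me3).

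With the strongest 50% of each list, shared shares were 47.7% (NSC H3K4me3), 99.2% (Neuron H3K4me3), 63.6% (NSC H3K27me3) and 59.4% (Neuron H3K27me3). With equal numbers of peaks, shared shares were 71.1% (NSC H3K4me3), 74.3% (Neuron H3K4me3), 56.9% (NSC H3K27me3) and 68.1% (Neuron H3K27me3). With a minimum width of 1 kb, shared shares were 81.9% (Neuron H3K4me3). With merging below 1 kb, shared shares were 39.0% (NSC H3K4me3), 65.5% (NSC H3K27me3) and 59.8% (Neuron H3K27me3). With chromosome 1 left out, shared shares were 38.4% (NSC H3K4me3), 87.7% (Neuron H3K4me3) and 64.8% (NSC H3K27me3). With overlap of at least 50% of the shorter peak, shared shares were 62.1% (NSC H3K27me3) and 56.7% (Neuron H3K27me3). With reciprocal overlap of 50%, shared shares were 29.6% (NSC H3K4me3), 60.7% (Neuron H3K4me3), 33.1% (NSC H3K27me3) and 24.3% (Neuron H3K27me3).

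The strongest 50% of each list gave gene counts of 4342 (H3K4me3 lost), 420 (H3K4me3 gained) and 60 (both marks in neurons). Table peaks that overlap the start site gave gene counts of 98 (both marks in neurons). Table peaks within 5 kb gave gene counts of 277 (both marks in neurons). The table rule and absence within 10 kb gave gene counts of 864 (H3K4me3 lost), 63 (H3K4me3 gained), 65 (H3K27me3 lost) and 53 (H3K27me3 gained). The peak lists gave gene counts of 3598 (NSC H3K27me3), 3355 (Neuron H3K27me3), 156 (H3K4me3 gained), 668 (H3K27me3 gained), 1601 (both marks in NSCs) and 861 (both marks in neurons). The peak lists at FDR under 1e-20 gave gene counts of 2461 (NSC H3K27me3), 1813 (Neuron H3K27me3), 5004 (H3K4me3 lost), 35 (H3K4me3 gained) and 803 (both marks in NSCs). Equal numbers from the peak lists gave gene counts of 3598 (NSC H3K27me3), 3028 (Neuron H3K27me3), 259 (H3K4me3 gained), 1347 (both marks in NSCs) and 749 (both marks in neurons). The peak lists and absence within 10 kb gave gene counts of 114 (H3K4me3 gained) and 322 (H3K27me3 lost). The peak lists without chromosome 1 gave gene counts of 3222 (NSC H3K27me3), 2964 (Neuron H3K27me3), 113 (H3K4me3 gained), 582 (H3K27me3 gained), 1441 (both marks in NSCs) and 706 (both marks in neurons).

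Fates under the strongest 50% of each list were 35 (both), 82 (H3K4me3 only) and 166 (neither). Fates under table peaks that overlap the start site were 50 (both). Fates under table peaks within 5 kb were 134 (both). Fates under the table rule and absence within 10 kb were 21 (H3K4me3 only) and 4 (neither). Fates under the peak lists were 591 (both), 334 (H3K4me3 only) and 597 (H3K27me3 only). Fates under the peak lists at FDR under 1e-20 were 382 (H3K27me3 only) and 203 (neither). Fates under equal numbers from the peak lists were 517 (both), 361 (H3K4me3 only), 405 (H3K27me3 only) and 64 (neither). Fates under the peak lists and absence within 10 kb were 521 (H3K27me3 only) and 32 (neither). Fates under the peak lists without chromosome 1 were 491 (both), 305 (H3K4me3 only) and 567 (H3K27me3 only).

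For the strongest 50% of each list, list losses were 20 (cell cycle H3K4me3 lost) and 11 (astrocyte H3K4me3 lost). For table peaks that overlap the start site, list losses were 1 (synaptic H3K27me3 lost) and 10 (astrocyte H3K4me3 lost). For table peaks within 5 kb, list losses were 1 (synaptic H3K27me3 lost). For the table rule and absence within 10 kb, list losses were 5 (cell cycle H3K4me3 lost), 0 (synaptic H3K27me3 lost), 2 (Hox H3K4me3 lost), 0 (Hox H3K27me3 lost) and 0 (secreted signalling ligands H3K27me3 lost). For the peak lists, list losses were 5 (cell cycle H3K4me3 lost), 6 (synaptic H3K27me3 lost), 11 (Hox H3K4me3 lost), 1 (Hox H3K27me3 lost) and 1 (secreted signalling ligands H3K27me3 lost). For the peak lists at FDR under 1e-20, list losses were 23 (cell cycle H3K4me3 lost), 6 (synaptic H3K27me3 lost), 11 (astrocyte H3K4me3 lost) and 3 (Hox H3K27me3 lost). For equal numbers from the peak lists, list losses were 5 (cell cycle H3K4me3 lost), 8 (synaptic H3K27me3 lost), 1 (Hox H3K27me3 lost) and 2 (secreted signalling ligands H3K27me3 lost). For the peak lists and absence within 10 kb, list losses were 5 (cell cycle H3K4me3 lost), 0 (Hox H3K27me3 lost) and 0 (secreted signalling ligands H3K27me3 lost). Synaptic H3K27me3 losses, 6 by the peak lists, were 2 in that setting, as by the table rule, and so did not count as moved. For the peak lists without chromosome 1, list losses were 5 (cell cycle H3K4me3 lost), 6 (synaptic H3K27me3 lost), 11 (Hox H3K4me3 lost), 1 (Hox H3K27me3 lost) and 1 (secreted signalling ligands H3K27me3 lost).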

Other observations

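Gene families defined by symbol prefix after the fixed lists had been seen added some groups the report does not cover. Of 25 families, 20 had at least 15 scored genes, and counts are from the peak lists. Keratin genes, of epithelial cells, had H3K4me3 at 0 of 31 members in either cell type and H3K27me3 at 24 in NSCs and 18 in neurons, against about 5.97 and 5.54 in random lists. Genes were scored only if paired with a peak, so a family with little H3K4me3 may be scored largely through nearby H3K27me3 peaks. That can raise the H3K27me3 counts of keratin and collagen genes, and it was not tested. Collagen genes had H3K27me3 at 17 and 16 of 26, and H3K4me3 at 10 in NSCs and 3 in neurons. Of those 10, 7 had lost the mark, against 2.32 in width-matched random lists (0.06% as many) and 3.71 in fold-matched ones (2.1% as many). Potassium channel genes had H3K27me3 at 39 of 67 members in NSCs and 40 in neurons, and 7 of the 28 that lacked it in NSCs had gained it, against 1.4 in random lists, of which 0.02% gained as many. Such gains were not particular to channels. Solute carrier genes gained H3K27me3 at 16 of 180, against 6.74 (0.08% as many), and semaphorin genes at 3 of 11, against 0.52 (1.12%). Zinc finger genes of the Zfp series gained it at 2 of 270, against 9.01. They had H3K4me3 at 253 and 236 of 284 members and H3K27me3 at 14 and 10. All 56 histone cluster genes had H3K4me3 in NSCs and 47 had it in neurons. The 9 losses stood against 7.03 in width-matched random lists (25.1% as many) and 13.3 in fold-matched ones (94.8% as many). Mitochondrial ribosomal protein genes had H3K4me3 at 74 of 76 members in each cell type, and 0 had lost it.

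Clustered protocadherin genes had H3K4me3 at 10 of 16 members in NSCs and 12 in neurons. Of the 10, 3 had lost it, Pcdha6, Pcdhb1 and Pcdhb12, against 2.4 in random lists, and of the 6 without it in NSCs, 5 had gained it, against 0.18. The gains were Pcdhb2, Pcdhb3, Pcdhb5, Pcdhb6 and Pcdhb7, and all members lie on chromosome 18 and are named after their values were seen. The neuronal peaks of the gains held 68, 39, 45, 47 and 38 reads over 15, 19, 9, 21 and 13 input reads. The family was looked at after Pcdhb6 had been seen among the gains, and its members are similar in sequence and can share reads. Olfactory receptor genes gained H3K4me3 in neurons at 9 of 112 members (1.12% of random lists as many), and at 5 of 100 without chromosome 1 (12.4% as many).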
